A study of Mus musculus with 6 samples.

How the data were processed

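The series holds 6 RNA-seq libraries of mouse 4T1 mammary tumour cells, 3 from control cells and 3 from Carmil3 knockout cells, grouped by the titles and genotype labels. Per the labels' protocols, RNA was extracted with Trizol and libraries were made with a standard Illumina protocol. The authors deposited 1 table of values for 23644 Ensembl mouse genes, and these values have the form of FPKM: they are scaled by exon length and by read depth. The unit was read from the values, and whether reads or fragments were counted is not given in the sources used here. Per the submitters' processing notes, CASAVA, Bowtie, Bowtie2, TopHat2 2.0.12, TopHat and HTSeq 0.6.0 were used with the genome build mm10. The role of each tool, the annotation release, the strand setting and the rule by which genes were listed are not given in the sources used here. Without a known strand setting, reads of overlapping and antisense genes cannot be told apart, and reads of near-identical copies may be split between them.

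Identifiers were matched to GENCODE M21, an annotation of GRCm38, the assembly also called mm10. A symbol was found for 23587 rows and none for 57, and 12 rows share their symbol with another row. For most genes the deposited value multiplied by the union exon length of the annotation is a whole multiple of 1 step per library, which gave read totals between 17779131 and 19046816. Between 92.1% and 92.3% of the values of genes with up to 500 reads came out whole within 0.02 of a read. The reads summed over the listed genes came to between 108.7% and 109.1% of that total, so the total used by the authors is not the sum over the listed genes. The depths are therefore relative and approximate. The table rounds low values, so read numbers of genes with a few reads are approximate too.

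The design named limma on log2 values for a table of FPKM, and that branch was used because the table holds no counts. Values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (eBayes with trend and robust), on 11171 genes with at least 1 FPKM in at least 3 of the 6 libraries, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. A log2 change is on the log2(FPKM + 1) scale and understates the change of low genes. Scripts also used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Of the 35 gene lists fixed beforehand, 28 had at least 5 tested members and were tested with camera at a preset correlation of 0.01, with adjustment over the lists. With an estimated correlation 2 lists were called, the epithelial and the cholesterol list. Pairs of libraries within a group differed by more than sampling noise (chi-square per degree of freedom between 2.93 and 18.51 on genes with at least 100 reads), so all 6 were counted as separate libraries.

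Genes were named by a rule written beforehand: the CARMIL genes; the 8 largest rises and 8 largest falls among called genes whose groups do not overlap and whose higher mean is at least 5 FPKM, leaving out names without a given symbol; the 8 genes with the smallest adjusted p; up to 3 called members per direction of each list with a higher mean of at least 2 FPKM; and Cdh1, Cdh2, Vim, Snai1, Fn1 and Actb. For most lists fewer of these genes are described, a choice made after their values were seen. They are mainly those whose calls held under the alternatives other than the test against a 1.5-fold change. That test ended the calls of 95 of the genes named by the rule, many of the described ones included. Some genes that the rule names are not reported here.

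Alternatives fixed before the data were examined were pseudocounts of 0.1 and 5, no filter and a filter of 5 FPKM, median-of-ratios rescaling, quantile normalization, eBayes without trend and robust, a test against a 1.5-fold change, the replicate number as a block, each library left out in turn, camera with an estimated correlation, and fry. Alternatives added after seeing the data were limma-voom on the recovered reads and centring on neighbours, in which the median log2 change of the 20 nearest tested genes on each side was subtracted. Keeping the tested genes when a library was left out was also decided after seeing the data, because filtering the remaining libraries again dropped genes expressed in only 1 group. Tests that need deposited counts were not run.

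The fit was tested on simulated data: reads were drawn at the depths of the 6 libraries, and of 10379 genes that then passed the filter 65 were changed 1.5-fold, 66 were changed 2-fold and 63 were changed 4-fold. At a 1.5-fold change 92.3% of the changed genes were recovered, at 2-fold 100%, and at 4-fold 100%; 12 unchanged genes were called, 6% of the calls. A simulated shifted list was called and 0 of 20 lists of unchanged genes were called. The simulated genes were drawn independently, so this does not show how the preset correlation fares on lists with correlated members. They also shared 1 dispersion (0.00276), and no simulated library was set apart from its group. The real knockout replicate 3 differed from its replicates at 18.51 and 17.17 chi-square per degree of freedom. The simulated shares of recovered and false calls may therefore not hold for these data. In 98% of 200 simulated steps of 0.5 on the log2 scale, the change point fell within 3 genes of the true place. Each had 56 genes before the step and 47 after it, as in the chromosome 14 result, with independent normal noise. Stretches with no step or with several steps were not simulated.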

Results

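Gene expression was measured by RNA sequencing in 4T1 cells, a mouse mammary tumour cell line, with and without a knockout of Carmil3. Carmil3 belongs to the CARMIL family of proteins, which bind actin capping protein and regulate actin filament ends at the cell membrane. There were 3 control libraries and 3 knockout libraries, and per the labels the knockout cells were grown from single cells. The labels do not say how the knockout was made, how many clones were sequenced, or that the 3 libraries of a group came from separate cultures. The p-values therefore measure the spread between these samples, which may be technical. The deposited table lists FPKM for 23644 genes. Read totals recovered from the spacing of the values were 18183057, 17779131 and 18719088 reads for the control libraries and 19046816, 18505152 and 18139161 reads for the knockout libraries. The question addressed was which transcripts differ between control and Carmil3 knockout cells.

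Carmil3 (ENSMUSG00000022211, chromosome 14, 55490651 to 55508272 on the plus strand, GRCm38) was close to the lower limit of the measurement in every library. It was listed at 0.036, 0.025 and 0.012 FPKM in control replicates 1 to 3 and at 0, 0.012 and 0.024 FPKM in knockout replicates 1 to 3. With the annotated exon length these values round to 4, 3 and 1 reads in the control libraries and 0, 1 and 3 reads in the knockout libraries. For this gene they did not come out whole in every library. The listed values are spaced by about 0.012 FPKM, so these read numbers are uncertain and may be too high. The means were 0.0241 ± 0.0122 FPKM in control and 0.0120 ± 0.0120 FPKM in knockout cells (SD, n = 3). A two-sided exact permutation test gave p = 0.3, where the smallest p that 3 against 3 samples allow is 0.1. By that length, 1 FPKM of the gene would have given between 114.8 and 123 reads per library, and fewer if the authors used a shorter length. Either way the transcript was too rare in the control cells for a loss to be detectable at this depth. Its level does not check the labels. The paralog Carmil1, on chromosome 13, measured 3.72 ± 0.119 FPKM in control and 3.17 ± 0.266 FPKM in knockout cells (SD, n = 3), a log2 change of -0.18 with adjusted p = 0.0756 by limma with Benjamini-Hochberg adjustment. That difference passed the threshold with limma-voom on the recovered reads (adjusted p = 0.0337) and with centring on neighbouring genes (adjusted p = 0.0272). Both of these settings were chosen after seeing the data. The difference did not pass with pseudocounts of 0.1 or 5, without the filter, with median-of-ratios rescaling or with quantile normalization. Nor did it pass with eBayes without trend and robust, with the replicate number as a block, or with any library left out. Carmil2 measured 0.0867 ± 0.0231 FPKM in control and 0.0651 ± 0.0232 FPKM in knockout cells (SD, n = 3) and was below the expression filter.

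Among the genes with the largest rises in the knockout cells were chemokine and complement genes, and among those with the largest falls were genes of epithelial keratins and junctions. Lcn2, which encodes the secreted iron-carrier-binding protein lipocalin-2, rose from 2.14 ± 0.200 to 279 ± 26.2 FPKM (SD, n = 3), a ratio of 130. Cxcl5 and Cxcl1, chemokines that attract neutrophils, rose from 17.0 ± 1.26 to 558 ± 55.9 FPKM and from 6.77 ± 0.591 to 146 ± 11.8 FPKM. Krt7, an epithelial keratin, fell from 27.9 ± 2.30 to 0.149 ± 0.0541 FPKM, and Epcam, an epithelial adhesion molecule, fell from 19.7 ± 0.0502 to 0.0875 ± 0.0544 FPKM. Cdh1, which encodes E-cadherin, fell from 12.4 ± 0.245 to 0.773 ± 0.0434 FPKM, a ratio of control to knockout of 16.1.

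Other large rises were found for the complement genes C3 and C1s1, with ratios of knockout to control of 28.3 and 20.5. The granulocyte colony-stimulating factor gene Csf3 rose 6.64-fold, the adhesion receptor gene Sele (E-selectin) 6.21-fold and the secreted glycoprotein gene Stc1 5.14-fold. The 8 genes with the largest rise had log2 changes of (FPKM + 1) between 2.23 for Stc1 and 6.48 for Lcn2, and limma's Benjamini-Hochberg adjusted p lay between 1.12e-09 for Lcn2 and 1.26e-07 for Stc1. Cldn4 fell from 20.3 ± 1.58 to 0.0299 ± 0.0304 FPKM and Cldn3 from 22.9 ± 2.52 to 1.87 ± 0.213 FPKM, and both encode tight-junction claudins. Perp, a desmosome-associated membrane protein gene, fell from 12.7 ± 0.457 to 0.0281 ± 0.0282 FPKM. Lad1 and Gpc4, which encode ladinin-1 and a glypican, had log2 changes of -3.41 and -3.12. The 8 genes with the largest fall had log2 changes between -3.06 for Cldn3 and -4.65 for Krt7. On GRCm38, Lcn2 lies on chromosome 2 (32384633 to 32388252), Cxcl5 and Cxcl1 on chromosome 5 (90759360 to 90761624 and 90891241 to 90893115), Krt7 on chromosome 15 (101411043 to 101430313), Epcam on chromosome 17 (87635979 to 87651129) and Cdh1 on chromosome 8 (106603351 to 106670246).

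**Figure D1:**
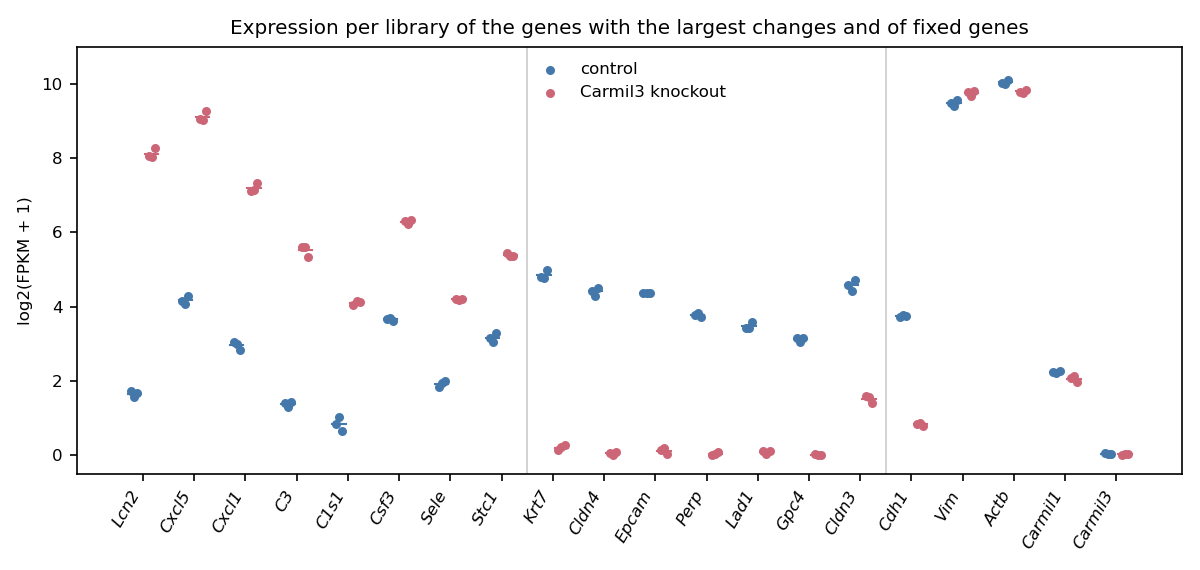
Expression per library, as log2(FPKM + 1), of the 8 genes with the largest rise, 7 of the 8 with the largest fall, and Cdh1, Vim, Actb, Carmil1 and Carmil3. Each point is 1 library (control blue, knockout red, 3 each) and each bar is a group mean; the control and knockout points do not overlap for Lcn2, with group means of 2.14 and 279 FPKM, or for Krt7, with 27.9 and 0.149 FPKM. The largest rises and falls were chosen among genes whose groups do not overlap, so this holds by the rule.

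Of 11171 genes tested, 1886 were higher and 2087 lower in knockout cells at an adjusted p under 0.05 (limma on log2(FPKM + 1), Benjamini-Hochberg adjustment over all genes tested). A log2 change of at least 1 was found for 106 of the higher and 160 of the lower genes, and these counts depend on the pseudocount: with a pseudocount of 0.1 they were 178 and 258, and with 5 they were 32 and 35. Tested against a 1.5-fold change, 118 genes were higher and 193 lower. The values of the groups did not overlap for 5644 genes, 50.5% of those tested, where chance gives 10%. On the first principal component, with 71.4% of the variance, the groups stood apart; on the component with 11.8%, knockout replicate 3 lay at -15.55 and the other knockout libraries at 6.73 and 9.56. Without control replicate 1 the counts were 1182 higher and 1358 lower. Changes also followed chromosome position: genes with a mean of at least 5 FPKM had a median log2 change of -0.22 on chromosome 8 and 0.19 on chromosome 6, and after each gene was centred on its neighbours 2961 genes were called, 2424 of them shared with the uncentred calls.

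**Figure D2:**
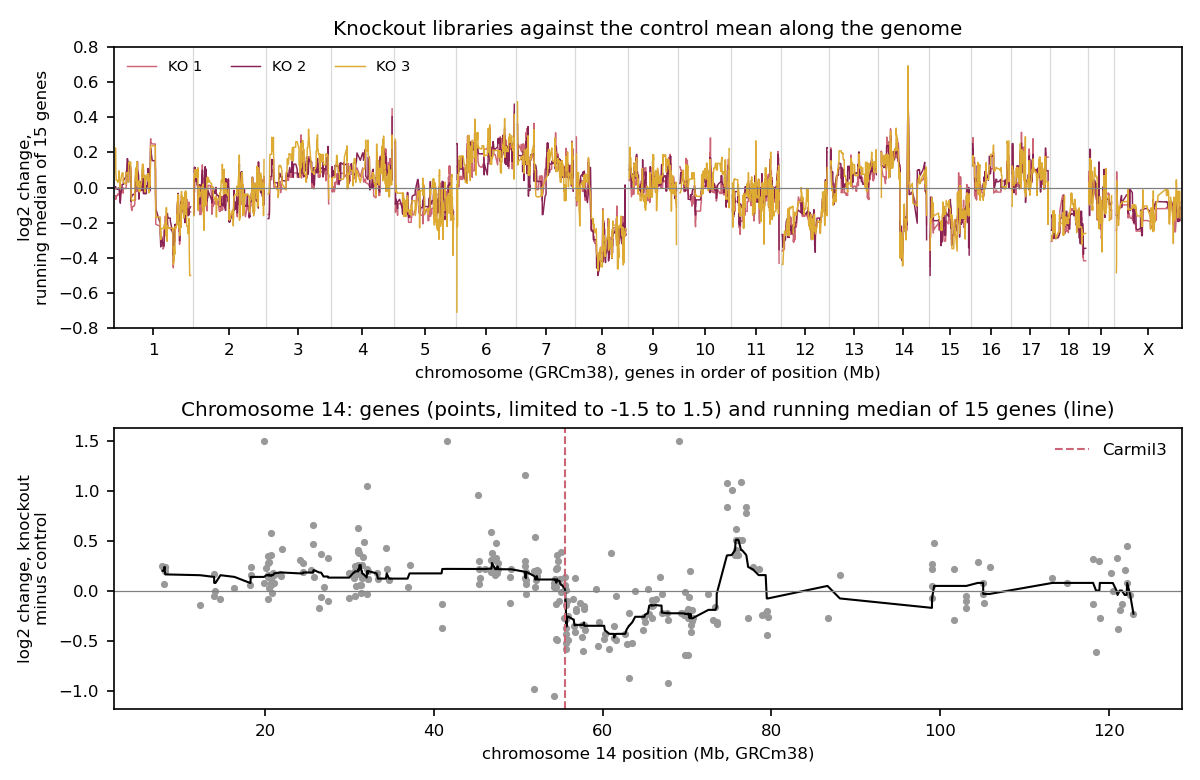
Log2 change of (FPKM + 1) along the genome for genes with a mean of at least 5 FPKM, as running medians of 15 genes for each knockout library against the control mean (upper panel, chromosome on the x axis), and for single genes on chromosome 14 with their running median (lower panel, position in Mb on the x axis, points limited to the range drawn). The lines of the 3 knockout libraries follow each other, with chromosome 8 at medians of -0.21, -0.23 and -0.23. All 3 lines are set against the same control mean, so part of their likeness is built in. The dashed line marks Carmil3.

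Epithelial junction and identity genes fell as a group. Of 31 members tested, 27 fell, 2 rose and 2 did not pass the test, and the counts adjusted over the list alone were also 27 and 2. Besides Krt7, Cldn4, Epcam and Cdh1, the simple-epithelial keratin gene Krt18 fell from 522 ± 24.7 to 227 ± 14.8 FPKM. The members that rose were Elf3, an epithelial transcription factor gene (log2 change 1.06), and Ocln, which encodes occludin (0.53). The median log2 change of the list was -1.20, camera gave an adjusted p of 1.01e-16, and the adjusted p was 0.0446 with an estimated correlation. The list of basal and luminal mammary genes did not move in 1 direction: 4 of 10 tested members rose and 6 fell, the same counts as adjusted over the list alone, with falls of Krt14 (log2 change -1.91) and Krt19 (-1.59) and rises of Lcn2 and Sox9 (0.83). Its median log2 change was -0.46 and its mean 0.12, and camera gave an adjusted p of 0.472.

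Mesenchymal genes and regulators of epithelial-mesenchymal transition went both ways. Of 17 tested members 5 rose and 7 fell, the same counts as adjusted over the list alone (7 and 5 after centring on neighbouring genes), and camera gave an adjusted p of 0.671; without the expression filter the list was called lower, with adjusted p = 0.0213. The receptor tyrosine kinase gene Axl rose from 153 ± 6.40 to 250 ± 11.9 FPKM and the transcription factor gene Zeb2 from 5.11 ± 0.168 to 7.02 ± 0.424 FPKM. Pdgfrb (log2 change -1.78) and Col6a1 (-1.32) fell. Vim, which encodes vimentin, rose from 721 ± 36.9 to 863 ± 37.5 FPKM, with an adjusted p of 0.0174 by limma with Benjamini-Hochberg adjustment; this call was lost without control replicate 1 (adjusted p = 0.077), control replicate 2 (0.0547) or knockout replicate 1 (0.0577). Snai1 measured 9.01 ± 1.58 and 8.43 ± 1.48 FPKM (adjusted p = 0.672, limma) and Fn1 125 ± 4.71 and 123 ± 22.3 FPKM (adjusted p = 0.882, limma) in control and knockout cells. Cdh2 was not analysed here.

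Cytokines, chemokines and NF-kB targets rose. Of 28 tested members 20 rose, 5 fell and 3 did not pass, with the same counts adjusted over the list alone. Lcn2, Cxcl5, Cxcl1 and Csf3 led the rises. Ptgs2, the inducible cyclooxygenase gene, fell from 46.7 ± 1.24 to 24.6 ± 1.02 FPKM, and the chemokine gene Cx3cl1 fell from 16.8 ± 1.30 to 9.15 ± 0.508 FPKM. The median log2 change was 0.44 and camera gave an adjusted p of 5.06e-08; the call was lost with adjusted p = 0.082 with an estimated correlation. Interferon-stimulated genes did not move together: 2 of 23 rose and 3 fell, also when adjusted over the list alone (with 1 library left out 1 to 3 rose and 1 to 2 fell), with Isg15 at a log2 change of 0.77 and Ifit2 at -1.30, and camera gave an adjusted p of 0.608. Genes of MHC class I antigen presentation were lower as a list, with 9 of 20 members fallen and 2 risen (10 and 2 adjusted over the list alone, 7 and 1 without control replicate 1). H2-Q7 (log2 change -0.69), H2-Q6 (-0.57) and the immunoproteasome gene Psmb8 (-0.56) fell and H2-T23 rose (0.91); reads can be shared between these near-identical H2 genes, so their single values are uncertain. Camera gave an adjusted p of 0.0162 for that list, which became adjusted p = 0.564 with an estimated correlation and 0.053 with a filter of 5 FPKM.

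Cholesterol genes fell almost throughout. Of 23 tested genes of cholesterol biosynthesis and uptake, 21 fell, none rose and 2 did not pass; 22 fell when adjusted over the list alone. Msmo1, a sterol oxidase gene, fell from 21.4 ± 0.476 to 7.92 ± 1.10 FPKM, Insig1, a sterol-sensing regulator gene, from 54.7 ± 0.883 to 22.1 ± 0.640 FPKM, and Cyp51, the lanosterol demethylase gene, from 27.6 ± 1.18 to 11.2 ± 0.543 FPKM. The median log2 change was -0.69, camera gave an adjusted p of 4.77e-14, and the adjusted p was 0.0332 with an estimated correlation. In the list of fatty acid synthesis and lipid storage 11 of 23 members fell and 2 rose, with the same counts adjusted over the list alone. With 1 library left out 9 to 11 fell and 1 to 2 rose. The desaturase genes Scd1 and Fads2 had log2 changes of -0.84 and -0.64, Me1 had -0.69, and Dgat2, a triglyceride synthesis gene, rose by 0.52. Camera gave an adjusted p of 0.00807, and the call was lost with adjusted p = 0.203 with an estimated correlation.

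Genes that respond to YAP and TAZ, and targets of the actin-regulated factors MRTF and SRF, were lower as lists. Of 23 tested YAP-TAZ targets 14 fell and 4 rose (15 and 5 adjusted over the list alone): Ccn2, a matricellular growth factor gene, fell from 9.81 ± 0.330 to 1.56 ± 0.0815 FPKM, Nt5e and Dock5 fell (log2 changes -0.94 and -0.92), and Axl and Areg rose (0.71 and 0.35). The camera test had an adjusted p of 0.00151, which became adjusted p = 0.203 with an estimated correlation. After centring on neighbouring genes the median log2 change of the YAP-TAZ list was -0.26 against -0.49 before. In that setting 13 members fell and 4 rose, and the adjusted p of camera was 0.00125. Of 22 tested MRTF-SRF targets 7 fell and 1 rose (9 and 1 adjusted over the list alone). Ankrd1 fell from 159 ± 6.24 to 91.2 ± 6.55 FPKM and Egr1 rose by 0.44 on the log2 scale. By camera the adjusted p was 0.016, which became adjusted p = 0.203 with an estimated correlation. The beta-actin gene Actb fell from 1061 ± 44.2 to 891 ± 20.6 FPKM (adjusted p = 0.0144, limma with Benjamini-Hochberg adjustment), and the call was lost after centring on neighbouring genes (adjusted p = 0.0864) and without control replicate 1 (0.0687), control replicate 3 (0.0523) or knockout replicate 2 (0.0599).

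Lists closest to the known role of CARMIL proteins held members that rose and members that fell. Of 18 tested members of the CARMIL and actin capping list 3 rose and 5 fell, the same counts as adjusted over the list alone. After centring on neighbouring genes 1 member, Add3, rose and 5 fell; the counts were 1 and 3 without control replicate 1 and 3 and 3 without knockout replicate 2. Add3, an adducin gene, rose 1.86-fold (log2 change 0.80) and Gsn, which encodes the actin-severing protein gelsolin, fell from 45.1 ± 3.03 to 25.8 ± 2.07 FPKM; camera gave an adjusted p of 0.952. Of 40 tested genes of actin nucleation and turnover 6 rose and 15 fell (7 and 16 adjusted over the list alone, 4 and 8 after centring on neighbouring genes), with Enah and Brk1 higher (log2 changes 0.63 and 0.53) and Daam1 and Arpc5 lower (-0.59 and -0.52). For this list the adjusted p of camera was 0.353. Of 33 tested focal adhesion and integrin genes 6 rose and 13 fell (7 and 14 adjusted over the list alone): Itga7 rose from 1.90 ± 0.260 to 7.02 ± 0.478 FPKM and Tns4 from 57.2 ± 3.22 to 130 ± 9.91 FPKM, and Fermt1 (log2 change -1.67), Itgb5 (-1.44) and Itgb1 (-0.66) fell. The adjusted p of camera was 0.0858. It was called lower without the expression filter (adjusted p = 0.011), after centring on neighbouring genes (0.0351) and without knockout replicate 1 (0.0457).

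**Figure D3:**
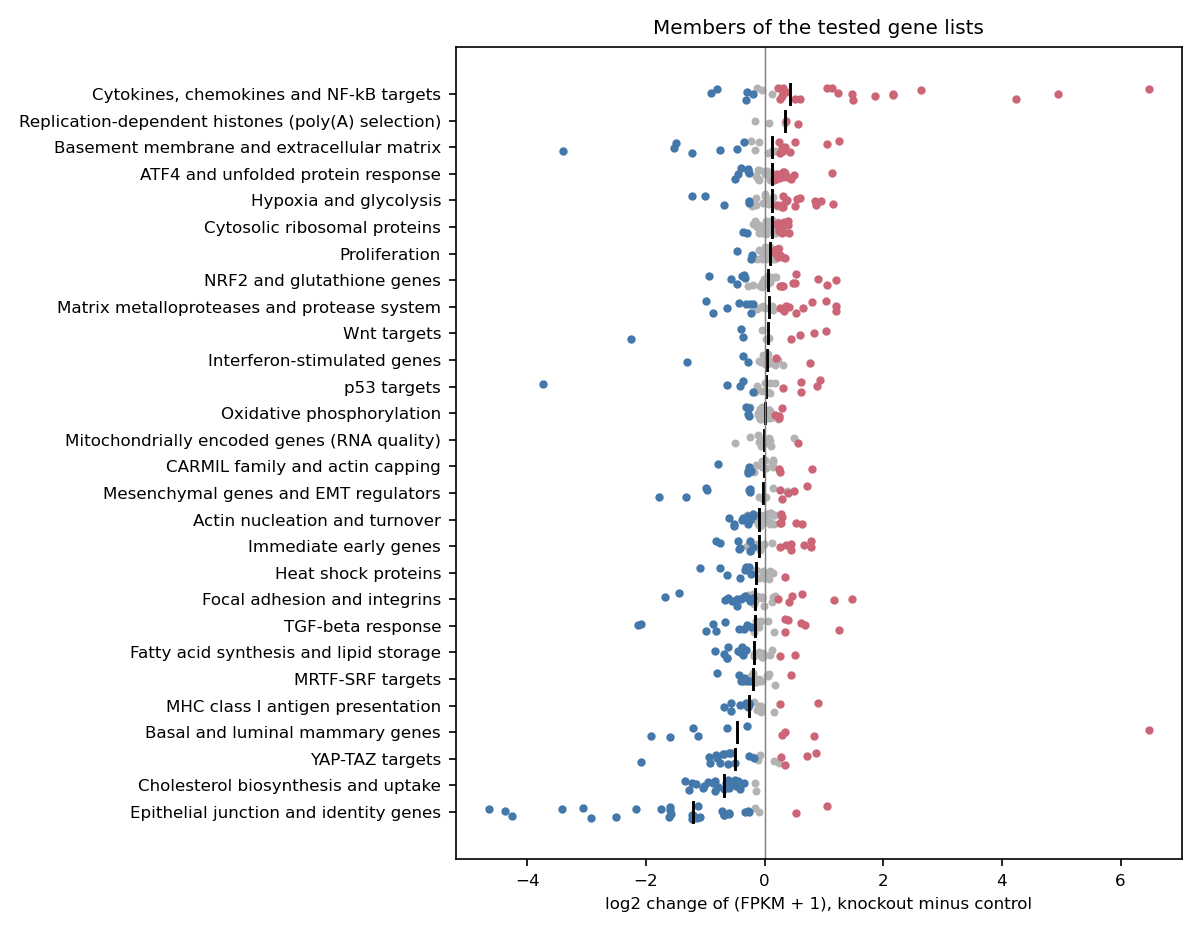
Log2 change of (FPKM + 1), knockout minus control, on the x axis for every tested member of the 28 tested gene lists (rows, ordered by median). Red points rose and blue points fell at an adjusted p under 0.05 (limma, Benjamini-Hochberg), grey points did not pass, and black bars are medians, which run from -1.20 for epithelial genes to 0.44 for cytokines.

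Matrix and protease genes were mixed. In the protease list 10 of 25 tested members rose and 8 fell, the same counts as adjusted over the list alone (9 and 5 without control replicate 1), and camera gave an adjusted p of 0.439. Mmp9, the gelatinase B gene, rose from 34.6 ± 2.97 to 80.4 ± 1.77 FPKM and the heparanase gene Hpse from 2.21 ± 0.215 to 6.39 ± 0.488 FPKM, and Mmp10 fell (log2 change -0.86). In the basement membrane and matrix list 9 of 23 rose and 7 fell (10 and 8 adjusted over the list alone, 5 and 7 without control replicate 1 or 2, 5 and 8 without knockout replicate 1). Ltbp2 (log2 change 1.26) and Tinagl1 (1.05) rose, and Thbs1 (-1.52) and Col7a1 (-1.23) fell. The median of that list was 0.13 and its mean -0.19, and camera gave an adjusted p of 0.952. Of 23 tested TGF-beta response genes 6 rose and 10 fell (7 and 12 adjusted over the list alone): Pmepa1 fell from 3.94 ± 0.248 to 0.120 ± 0.0363 FPKM and Id2 rose (log2 change 0.68). By camera the adjusted p was 0.126, and without the expression filter the list was called lower (adjusted p = 0.0382). Of 10 tested Wnt targets 4 rose and 3 fell, also when adjusted over the list alone, with the cyclin gene Ccnd1 higher (log2 change 1.04) and Ccn4 lower (-2.25); camera gave an adjusted p of 0.439.

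Proliferation genes were slightly higher as a list. Of 40 tested members 10 rose and 3 fell (9 and 3 adjusted over the list alone, 5 and 2 without control replicate 1), with Nusap1 and Kif23 at log2 changes of 0.35 and 0.26 and the replication helicase gene Mcm5 at -0.46. Camera gave an adjusted p of 0.0162, which became adjusted p = 0.203 with an estimated correlation and 0.124 with quantile normalization. In the hypoxia and glycolysis list 15 of 36 tested members rose and 5 fell (17 and 7 adjusted over the list alone). The hexokinase gene Hk2 rose from 18.9 ± 0.226 to 43.5 ± 1.89 FPKM, and Ero1l and Pfkfb3 rose (log2 changes 0.96 and 0.87), whereas the hypoxia-induced genes Car9 (-1.22) and Ddit4 (-0.68) fell. Camera gave an adjusted p of 0.0153, and the call was lost with adjusted p = 0.743 with an estimated correlation. Of 19 tested heat shock protein genes 9 fell and 1 rose, also when adjusted over the list alone, and after centring on neighbouring genes 5 fell and 1 rose, with the median log2 change at -0.08 against -0.15: Hsph1 had a log2 change of -1.09, Hspa4l -0.75 and Dnajb4 0.34. Camera gave an adjusted p of 0.0228, and the call was lost with adjusted p = 0.564 with an estimated correlation and without knockout replicate 1 (0.0644) or 2 (0.055). Of 61 tested cytosolic ribosomal protein genes 15 rose and 2 fell (12 and 2 adjusted over the list alone), with Rpl22 at a log2 change of 0.39. These counts were 2 and 0 after centring on neighbouring genes, 4 and 1, 4 and 3, and 15 and 1 without control replicates 1, 2 and 3, and 7 and 1, 12 and 1, and 9 and 7 without knockout replicates 1, 2 and 3. Camera gave an adjusted p of 0.0162, which became adjusted p = 0.878 with an estimated correlation, 0.142 with quantile normalization, 0.0975 without control replicate 2 and 0.396 without knockout replicate 3, the library that stood apart on the second component.

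The lists of ATF4 and unfolded protein response, NRF2, p53, immediate early and oxidative phosphorylation genes were not called by camera. Of 33 tested ATF4 and unfolded protein response genes 12 rose and 6 fell, also when adjusted over the list alone, with the cystathionase gene Cth at a log2 change of 1.14 and Sel1l at -0.49, and camera gave an adjusted p of 0.126. Of 28 tested NRF2 and glutathione genes 9 rose and 6 fell, also when adjusted over the list alone. The glutathione transferase genes Gstm1 and Gsta4 rose (log2 changes 1.21 and 1.05) and Nqo1, a quinone reductase gene, fell from 24.0 ± 1.62 to 12.2 ± 1.07 FPKM; camera gave an adjusted p of 0.393. Of 18 tested p53 targets 5 rose and 5 fell (6 and 5 adjusted over the list alone), with Plk2 at 0.94 and Tnfrsf10b at -0.63. The largest fall in this list was that of Perp, described above. The median log2 change was 0.03 and the mean -0.1, and camera gave an adjusted p of 0.831. Of 24 tested immediate early genes 7 rose and 8 fell, also when adjusted over the list alone (6 and 3 after centring on neighbouring genes, 6 and 5 without control replicate 1 or knockout replicate 1, 7 and 5 without knockout replicate 2), with Dusp4 and Fosl1 at log2 changes of 0.79 and 0.78 and Jund at -0.81, and camera gave an adjusted p of 0.831. Of 38 tested oxidative phosphorylation genes 4 rose and 4 fell, 0 and 0 adjusted over the list alone, and camera gave an adjusted p of 0.831. Those counts were 0 and 3 after centring on neighbouring genes, 0 and 1, 0 and 5, and 1 and 2 without control replicates 1, 2 and 3, and 2 and 0 and 1 and 5 without knockout replicates 2 and 3.

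Markers of other cell types and of RNA quality showed no shared rise. Of the fibroblast markers 3 were tested: Pdgfra rose from 10.1 ± 0.135 to 17.6 ± 0.272 FPKM, and Pdgfrb and Col1a1 fell, also when adjusted over the list alone. Of 3 tested myeloid markers S100a8, a calprotectin subunit gene, and Cd14 fell (log2 changes -2.33 and -0.64; for Cd14 adjusted p = 0.0622 without control replicate 1 and 0.0561 without control replicate 3, limma); the counts were the same adjusted over the list alone. Of 3 tested endothelial markers Flt1 rose (log2 change 0.65), and adjusted over the list alone 1 rose and 1 fell. Of the lymphocyte markers and of the sex-chromosome genes 0 were tested, because those in the table lay below the expression filter. Of 14 tested mitochondrially encoded genes 1 rose, mt-Nd6 (log2 change 0.56), also when adjusted over the list alone, camera gave an adjusted p of 0.929, and the mitochondrial share of reads was between 2.5% and 2.9% per library. Of 5 tested replication-dependent histone genes Hist1h1c and Hist1h2bc rose (log2 changes 0.56 and 0.36), also when adjusted over the list alone, and camera gave an adjusted p of 0.32.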

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

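Limma-voom on recovered reads and centring on neighbours were chosen after seeing the data, as was keeping the tested genes when a library was left out; the other alternatives were planned. Genes called both here and under any alternative had the same direction in each. Counts with a log2 change of at least 1 (106 higher, 160 lower) were 65 and 70 with a filter of 5 FPKM, 178 and 258 with a pseudocount of 0.1, 32 and 35 with a pseudocount of 5, and 178 and 241 with limma-voom; the pseudocounts and the filter act on low genes by construction. Against a 1.5-fold change 118 genes were higher and 193 lower, since this test asks for a larger change. With 1 library left out the counts ranged from 1182 to 2041 higher and from 1358 to 2218 lower; the lowest were without control replicate 1, with 2511 of 2540 calls shared, and the cause was not tested. The difference of Carmil3 in mean log2 value was -0.149 with a pseudocount of 0.1, against -0.0172, and rests on a few reads per library at most. Lists called (4 higher, 7 lower) were 2 higher with quantile normalization, 11 lower without a filter, 0 higher and 2 lower with an estimated correlation, and 13 lower with fry, which does not compare a list with other genes; the cause was not tested for the first 2. Fry gave lower values for the basement membrane list (adjusted p = 0.0124) and the p53 list (adjusted p = 0.00143), where camera's uncalled direction was higher. Mcm6, lower in the knockout, had a log2 change of 0.02 (adjusted p = 0.795, limma) after centring on neighbours, where the median log2 change of its neighbours was -0.25. The replicate block called 4027 genes, 3671 of them shared, and changed the call of 1 named gene, Ndufab1 (adjusted p = 0.0713, limma). Deviations of same-numbered libraries correlated at -0.061, 0.149 and 0.098 for replicates 1, 2 and 3. In both groups the libraries of replicates 2 and 3 matched their own number best, and those of replicate 1 did not. These values do not settle whether the numbers pair the samples. Depth limits Carmil3 and other genes of a few reads.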

Other observations

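The tests of the germline and imprinted lists, the estimated correlation for the fixed lists, leaving out a library (apart from keeping the tested genes) and the test on GC content and length were planned before their results were seen. The family test, centring on neighbours, the tests on chromosome stretches, on the step beside Carmil3, on other cell types and on other splits of the libraries, and the choice of the genes at segment ends were made after the results they bear on had been seen.

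Germline and imprinted genes were rarely expressed in either group. Of 2 tested germline genes the X-linked homeobox gene Rhox5 fell from 3.16 ± 0.406 to 0.261 ± 0.0757 FPKM (SD, n = 3), and 2 fell when adjusted over the list alone. Of 4 tested imprinted genes 2 fell, also when adjusted over the list alone: Phlda2, a placental growth regulator gene, from 5.23 ± 0.650 to 1.47 ± 0.252 FPKM, and Impact, whose call was lost after centring on neighbours (adjusted p = 0.77, limma) and without control replicate 1 (0.0646) or knockout replicate 2 (0.0599). Among 158 groups of at least 8 tested genes sharing the stem of their symbol, 0 were called by camera after Benjamini-Hochberg adjustment; the smallest adjusted p was 0.219, 19 had an unadjusted p under 0.05, and 1 did with an estimated correlation.

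The knockout libraries differed from the control libraries along whole chromosome stretches. Over 7304 genes with a mean of at least 5 FPKM, the medians of the log2 change were lowest on chromosomes 8, 18 and 12 (-0.22, -0.19 and -0.16) and highest on chromosomes 6, 7 and 3 (0.19, 0.15 and 0.12), and their SD over 20 chromosomes was 0.119, above the highest of 1000 shuffles of the changes over genes (0.0248). A correction for GC content and length left 100.1% of that SD, which argues against such a bias. Breaks lay inside chromosomes too: the medians of 20 genes on each side went from 0.25 to -0.28 between Bcl2 and Kdsr on chromosome 1 and from -0.25 to 0.46 between Sucla2 and Esd on chromosome 14. A candidate explanation is that segment copy number differs between the knockout cells, grown from single cells, and the control cells; DNA copy number was not analysed here, so this stays a hypothesis.

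A step lay beside Carmil3 itself. Within 10 Mb, the change point fell between Psme2 and Ipo4 on chromosome 14, between 82.8 and 117.1 kb beyond the end of Carmil3. The median log2 change was 0.18 over 56 genes before it and -0.35 over 47 after it. The 95% bootstrap range, as the start of the first gene after the break, was 55578123 to 55657879. Carmil3 was too low to be among the genes scanned, and genes were resampled as independent around 1 step. The range therefore cannot show whether the break spares Carmil3. A step as large as at Carmil3 (-0.32) occurred at 0.9% of 6524 gene boundaries. Neighbouring boundaries share genes and the test was chosen after the step was seen, so this share is not a chance rate. A coincidence with a pre-existing break stays open. Genes 2 to 10 Mb beyond Carmil3 had a median of -0.35 (95% range -0.46 to -0.31), with 26 of 29 below 0, which argues against an effect limited to the nearest genes. A candidate explanation is a loss of chromosome 14 sequence that begins near the targeted gene, which DNA copy number would test. A loss alone leaves open the raised median in the 10 Mb before Carmil3 (0.19 over 54 genes) and the turn to higher medians between Sucla2 and Esd (-0.25 to 0.46). How the knockout was made and whether all 3 libraries come from 1 clone are not given in the labels.

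The fall of epithelial genes and the rise of inflammatory genes were weighed against technical causes. After centring on neighbours 28 epithelial members fell (27 before). The median log2 change was then -1.16 for the epithelial list (-1.20 before) and 0.47 for the cytokine list (0.44 before). These sizes argue against segment dosage as the whole cause. Camera gave adjusted p = 9.57e-21 for the epithelial list (1.01e-16 before, and 3.13e-15 uncentred without knockout replicate 3). For the cytokine list it gave adjusted p = 6.62e-09 (5.06e-08 before). The centred p-values leave out the uncertainty of the subtracted medians, so no conclusion is drawn from their being smaller. With an estimated correlation and without centring, the cytokine list was not called (adjusted p = 0.082) and the epithelial list was (0.0446). Cells of another type bring their abundant transcripts, and among 5 collagen and myeloid genes the highest knockout mean was 2.748 FPKM (Cd68, 3.18 FPKM in control), Col1a1 fell, and the mean of Lyz2 was 0.851 FPKM in control and 1.08 FPKM in knockout cells. Fibroblast markers moved apart, as Pdgfra rose from 10.1 to 17.6 FPKM and Pdgfrb fell from 9.49 to 2.06 FPKM. These values argue against added fibroblasts or myeloid cells as the whole cause; other cell types stay open. The real grouping called 3973 genes and the other splits of the 6 libraries at most 1; the real one was the 1 split of 10 with as many, and 10 splits cannot give a share under 0.05. Loss of Carmil3 and differences between clones that arose before or apart from it may each account for the pattern, and both stay open, because Carmil3 was near the lower limit in control cells and the labels do not tie libraries to clones.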
